A study of Mus musculus with 18 samples.

How the data were processed

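Total RNA from the right lung lobe of 18 female B6C3F1 mice was hybridised to Affymetrix Mouse Genome 430 arrays, 1 animal per array and 3 animals in each of 6 groups, per the labels. The mice were 18 weeks old when sampled, after 13 weeks of dosing, 7 days a week in feed or 5 days a week by gavage at 5 ml/kg, per the labels' protocols. RNA was purified and 10 µg of it labelled with biotin, per the labels' protocols. The animals carry numbers that name the arrays here (feed control 27, 28 and 29, corn oil control 22, 24 and 25, NDA 2, 4 and 5, NEDD 12, 14 and 15, PCNB 16, 18 and 20, benzofuran 6, 8 and 10), and no number occurs in more than 1 group.

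The deposited values are on a log2 scale. The scale was judged from their range of 2.48 to 14.78, since the base of the logarithm, the summary method and the normalization method are not given in the sources used here, and fold changes rest on base 2. The table held 45101 probe sets without missing values. The medians of the arrays lay between 5.678 and 5.802, a range of 0.124 and under the limit of 0.2 set beforehand, so that the values were kept as deposited. Scanner intensities and detection calls were not used here, and a low signal is therefore not told apart from background except by the filter below.

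Probe sets were named through the platform annotation, in which 34945 had a single gene symbol, 932 several and 9160 none here, beside 64 control probe sets. Of those with a single symbol, 34741 were matched by gene identifier to the RefSeq genes of assembly GRCm38.p6, and 0 symbols needed an update. Probe sets with several symbols or none named no gene. No coordinates are given, since no genome build is named for the array. Each gene was represented by the probe set with the highest mean over all arrays. A gene was tested if that probe set lay above its array's 40th percentile on at least 3 arrays, which left 13434 of 18193 genes. Other probe sets of a named gene can disagree with the one used, as 1 of 3 others for Srxn1, 1 of 2 for Afp and the other probe set of Wwox did by sign in the comparison of treatment classes.

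Gene-wise linear models with 1 mean per group were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with 12 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over genes within each of 8 comparisons. The p-values are two-sided, except the permutation p for 3' bias, which is one-sided. The class contrast is the mean of the NDA and benzofuran effects minus the mean of the NEDD and PCNB effects, each effect taken against its own control. Gene lists, 38 in all, were written before the data were examined, and 36 of them had at least 4 measured genes. They were tested with camera at a preset correlation of 0.01, with an adjustment over 288 tests (36 lists in 8 comparisons), and again with an estimated correlation and with fry. Camera called 94 of the 288 at the preset correlation and 9 with an estimated one, and fry called 43. Fry tests whether the genes of a list move on balance in 1 direction, without reference to other genes. Only those 9 calls hold in both camera versions, namely NRF2 targets for NDA, for the class contrast, for the positive groups against all others and for NDA against NEDD, AhR targets for NDA, for PCNB, for the positive groups against all others and for NDA against NEDD, and cell cycle genes for corn oil against feed control.

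Named genes followed a rule set before the data were examined. In a comparison of 3 arrays with 3 they are the called genes whose arrays do not overlap between groups, the 12 with the largest rise and the 12 with the largest fall; chance alone separates 10% of genes that way. For the class contrast both positive effects had to lie on the same side of both negative effects. For the positive groups against all others, all 6 arrays had to lie on the same side of the other 12, with 6 genes per direction. Clone names were skipped. Members of the gene lists were named up to 4 per list together with any called member, and the 5 genes with the smallest p where fewer than 5 were called. Cd79a, Ms4a1, Cxcl17, the NDA means of Cd79b and Fcmr and the benzofuran value of Asgr1 were chosen after their values were seen. So was the benzofuran value of Cyp1a1.

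The procedure was tested on simulated log2 data with the means and residual SDs of the real genes, in 5 runs with 200 of 13434 genes changed. For NDA against feed control it recovered 60.6% of genes changed 1.5-fold, 92.2% of those changed 2-fold and 99.7% of those changed 4-fold, with 4.3% of calls false. For the class contrast it recovered 74.9%, 96.1% and 100% at the same folds, with 6.2% of calls false. The simulated noise was independent between genes and equally wide in all groups. The real arrays were not so, with an array weight of 0.12 for benzofuran 10. These rates need not hold for comparisons that include benzofuran. The number of arrays, 3 per group, limits the precision. The median standard error was 0.131 for a comparison of 2 groups and 0.114 for the class contrast, on the log2 scale. No pair of arrays was close to identical, with a smallest median absolute difference of 0.107 between arrays of a group.

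The alternatives were median centring, quantile normalization, no filter or a stricter one at the 60th percentile, the mean of a gene's probe sets or the probe set of highest variance, a trended and robust prior, a fit of the compared groups only, array weights, the OD260/OD280 ratio of the RNA as a covariate, a minimum of 1.5-fold and leaving out each array in turn. Added after seeing the data were covariates for log2 OD260 and for the actin 3' minus 5' difference, tests of each probe set, array weights without benzofuran 10, lists without benzofuran 10, a t test over arrays of ciliated minus club cell genes, and a contrast of the NDA effect with the benzofuran effect. Overlaps of calls were set beside the overlap of independent lists and beside 100 simulations of unchanged groups with the same controls. Genes were drawn independently in these simulations. For genes, an array was left out only in comparisons that use its group. Named genes were not followed in the tests of each probe set or in the array weights without benzofuran 10. A named gene absent from a fit was not counted as lost. No hybridisation date or batch was used here. Figures were drawn with matplotlib 3.10.9.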

Results

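The study asked whether transcript levels in mouse lung after 13 weeks of treatment can foretell which chemicals give lung tumours in rodent bioassays of 2 years. Transcripts of the right lung lobe were measured on whole-genome arrays in female B6C3F1 mice, a hybrid strain used in such bioassays. The labels call 2 of the 4 chemicals positive lung carcinogens. These are 1,5-naphthalenediamine (NDA, 2000 ppm in feed) and 2,3-benzofuran (240 mg/kg by gavage in corn oil, 5 days a week). The other 2 are called negative and were both given in feed, N-(1-naphthyl)ethylenediamine dihydrochloride (NEDD) at 2000 ppm and pentachloronitrobenzene (PCNB) at 8187 ppm. Untreated feed was the control for NDA, NEDD and PCNB, and gavage with corn oil alone was the control for benzofuran. Each of the 6 groups held 3 mice, so that 18 arrays were compared, 1 per animal, and 13434 genes were tested. Signals are log2 values, and every fold change below is a difference of group means in limma, given with its standard error (n = 3 arrays per group unless stated). Adjusted p is limma's after Benjamini-Hochberg adjustment, with a threshold of 0.05. Permuting 3 animals against 3 cannot give a p below 0.1, so that the tests rest on the spread pooled over the 6 groups.

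**Figure D1:**
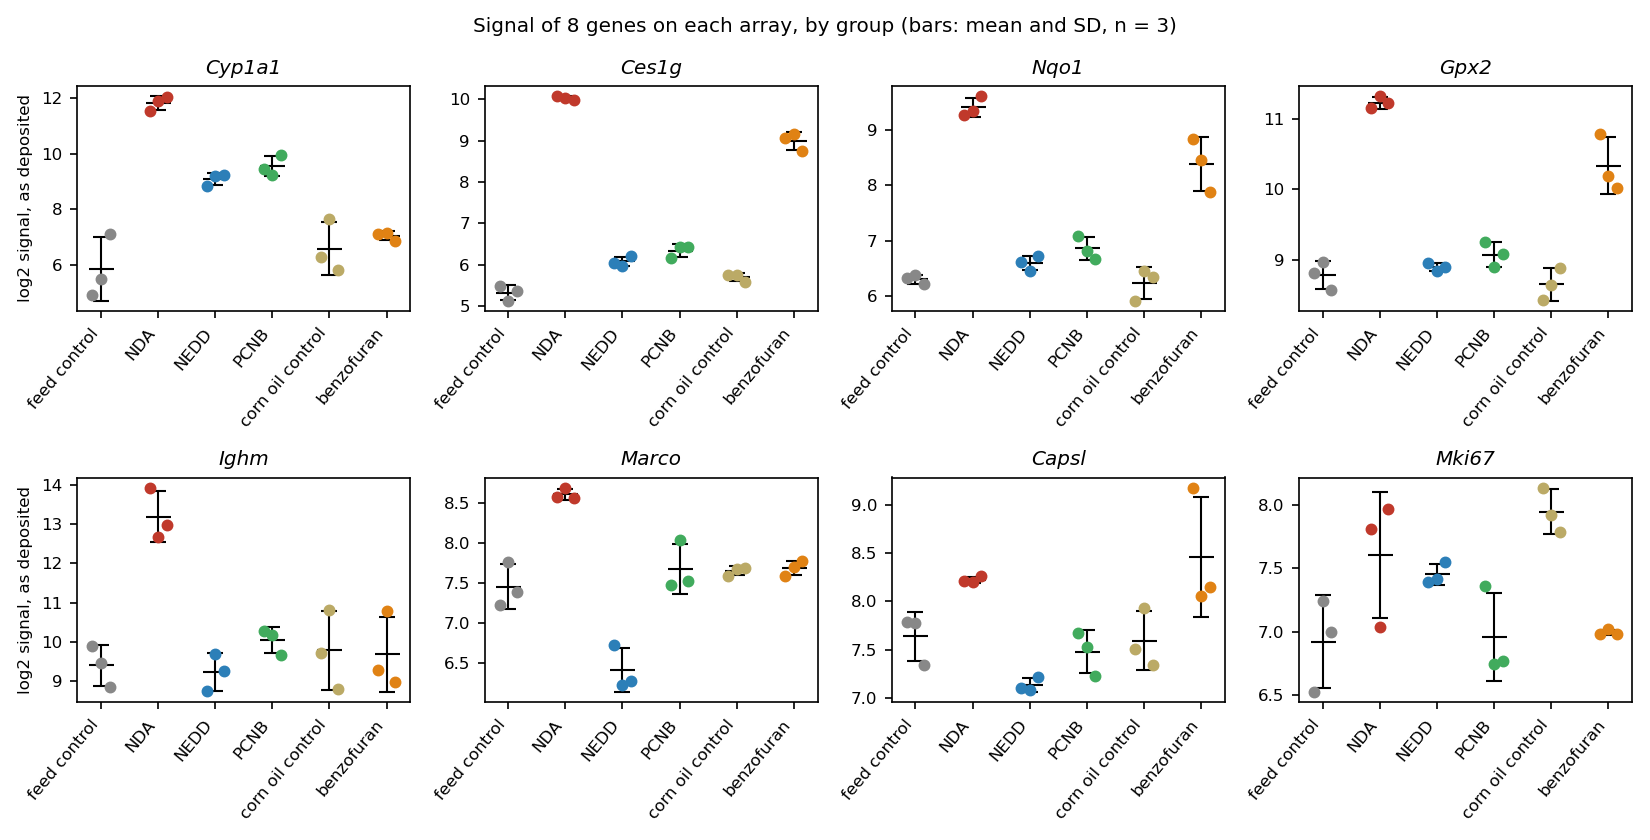
Log2 signal (vertical axis) of 8 genes on each of the 18 arrays, by group (horizontal axis). Each point is 1 array and the bars give the group mean and SD (n = 3). The 3 NDA arrays lie between 11.53 and 12.02 for Cyp1a1, against 4.93 to 7.12 for feed control.

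NDA gave the widest range of changes of the feed treatments. Cyp1a1, the monooxygenase induced through the aryl hydrocarbon receptor (AhR), was 62.2-fold higher than in feed control (log2 fold change 5.96 ± 0.44, adjusted p = 1.05e-07). Feed control signals of Cyp1a1 spread from 4.93 to 7.12. Its log2 fold change was 5.5 without feed control 27, 5.79 without feed control 28 and 6.59 without feed control 29. The carboxylesterase Ces1g was 26.2-fold higher (4.71 ± 0.12) and the quinone reductase Nqo1 8.56-fold higher (3.10 ± 0.19). Ighm, the heavy chain of IgM, rose by 3.78 ± 0.48 and Jchain, which links IgM and IgA into polymers, by 3.46 ± 0.48. Of the 184 genes called, 150 were higher and 34 lower.

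Among the gene lists fixed in advance were the targets of NRF2, the transcription factor of the oxidant response. Of 24 measured NRF2 targets, 21 rose with NDA over all genes tested (22 adjusted over the list alone), and none fell. They included the thioredoxin reductase Txnrd1 (1.54 ± 0.10), both subunits of the enzyme that begins glutathione synthesis (Gclm 1.47 ± 0.10, Gclc 1.42 ± 0.17), the sulfiredoxin Srxn1 (1.62 ± 0.15) and the heme oxygenase Hmox1 (1.53 ± 0.18). The list passed camera (adjusted p = 0.0025 with an estimated correlation). AhR targets rose in 4 of 5 measured genes (adjusted p = 0.0025 with an estimated correlation), namely Cyp1a1, Nqo1, Aldh3a1 and Cyp1b1. Nqo1 belongs to both lists. Of 24 phase I enzymes 9 rose and of 22 conjugating (phase II) enzymes 7 rose, Gsta2 by 1.99 ± 0.16. Neither list held its camera call once the correlation was estimated (adjusted p = 0.0804 with an estimated correlation for phase I and 0.117 for phase II).

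The other large rises with NDA were in Gp2 (4.28 ± 0.21), a membrane glycoprotein of antigen-sampling M cells and the pancreas, Tdo2 (3.72 ± 0.19), which opens the tryptophan ring, Cd177 (3.47 ± 0.23), known from the neutrophil surface, and Sptssb (2.88 ± 0.30), a subunit of serine palmitoyltransferase. The immunoglobulin genes Igk (3.31 ± 0.52), Igkv6-14 (3.17 ± 0.38) and Iglv1 (2.80 ± 0.47) completed the 12 largest. The feed control means of Gp2 (4.00) and Tdo2 (3.45) lay below the lower quartile of every feed control array, so that the size and rank of their differences, here and in the later comparisons, are uncertain. Of 11 B and plasma cell genes 3 rose, Ighm, Jchain and the plasma cell chaperone Mzb1 (1.88 ± 0.27), while the B cell surface genes Cd79a (0.37 ± 0.24) and Ms4a1 (0.15 ± 0.25) did not pass. The call of that list was lost with its correlation estimated (adjusted p = 0.227 with an estimated correlation). Of 14 alveolar macrophage genes the scavenger receptor Marco (1.15 ± 0.16) and the protease Ctsk (0.57 ± 0.11) rose. Single members rose in the lists of club cells (Upk3a, 1.40 ± 0.13), of the unfolded protein response (Trib3, 0.94 ± 0.13) and of p53 targets (Phlda3, 0.42 ± 0.10). None of 14 ciliated cell genes and none of 25 DNA repair genes were called. All 29 measured cell cycle genes were short of the threshold over all genes (17 higher adjusted over the list alone, median 0.42), and the list missed with its correlation estimated (adjusted p = 0.18 with an estimated correlation). Feed control also lay low on this list beside corn oil control and NEDD, though not beside PCNB.

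The falls with NDA were smaller. The largest were in Chad, a cartilage matrix protein (-1.60 ± 0.21), Asgr1, a glycoprotein receptor best known from hepatocytes (-1.32 ± 0.25), Lrrc26, a potassium channel subunit (-1.30 ± 0.18), Rbp7 (-1.27 ± 0.28), the bicarbonate transporter Slc4a5 (-1.25 ± 0.12) and the serotonin receptor Htr2b (-1.22 ± 0.17). Gbp3, an interferon-induced GTPase, was the only one of 19 interferon response genes called, at -0.64 ± 0.13. All 12 named rises kept their call without any 1 array of either group and under every alternative in which they were followed, whereas 4 of the 12 named falls did. The other probe set of Iglv1 was not called, while all 7 others of Ighm were. The count was 120 without feed control 29 and 755 with limma's array weights, 422 higher and 333 lower. The actin 3' minus 5' difference was 0.33 to 0.43 on NDA arrays and 0.58 to 0.73 on feed control arrays, and with it as a covariate 163 of the 184 genes stayed called among 361.

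NEDD, a naphthylamine like NDA but labelled negative, left most transcripts within the spread between animals. Cyp1a1 was 9.4-fold higher than in feed control (3.23 ± 0.44, adjusted p = 0.0118) and Ces1g 1.69-fold higher (0.76 ± 0.12, adjusted p = 0.0371). Marco was lower by a log2 fold change of -1.04 ± 0.16 (adjusted p = 0.0292), opposite to its rise with NDA. These 3 were the only genes called, and 1268 had an unadjusted p under 0.05, where 672 would be expected by chance. None of the 24 NRF2 targets was called. Ciliated cell genes lay lower, with a median of -0.32 over 14 genes, none of them called (4 adjusted over the list alone), and the list's camera call was lost with its correlation estimated (adjusted p = 0.378 with an estimated correlation). The next smallest p belonged to Dzank1 (-0.80 ± 0.15, adjusted p = 0.211) and to the mitotic gene Racgap1 (0.50 ± 0.10, adjusted p = 0.278), which did not pass.

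The NEDD calls were easily lost when an array was left out. No gene was called without feed control 28 or without NEDD 15, 1 was called without feed control 29 and 1 without NEDD 14, none was called when only both groups entered the fit, and 521 were called with array weights, 193 higher and 328 lower. The log2 fold change of Cyp1a1 was 2.77 without feed control 27, 3.06 without feed control 28 and 3.86 without feed control 29. Where its call was lost without feed control 28, its value thus stayed near the 3.23 of all arrays. With median centring 1 gene was higher and 1 lower.

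PCNB, a chlorinated fungicide, raised the same pair of genes that rose with NEDD. Cyp1a1 was 13-fold higher (3.70 ± 0.44, adjusted p = 0.00118) and Ces1g 2.01-fold higher (1.01 ± 0.12, adjusted p = 0.00118). No other gene was called, and 399 had an unadjusted p under 0.05, fewer than the 672 expected by chance. The AhR list passed through Cyp1a1 and smaller positive values of its 4 other members (adjusted p = 0.0307 with an estimated correlation). Interferon response genes lay higher in 17 of 19 cases, with a median of 0.27. Their camera call was lost with the correlation estimated (adjusted p = 0.064 with an estimated correlation) and none was called over all genes (4 adjusted over the list alone). Oas2 (0.63 ± 0.13, adjusted p = 0.582) and Oasl2 (0.55 ± 0.13) had the smallest p among them. All 24 NRF2 targets had positive values, none called, with a median of 0.20 and a lost camera call (adjusted p = 0.129 with an estimated correlation). The log2 fold change of Cyp1a1 was 3.23 without feed control 27, 3.52 without feed control 28 and 4.33 without feed control 29. Cyp1a1 and Ces1g stayed called without any 1 array of either group and were not called when the fit held only PCNB and feed control.

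Benzofuran was given by gavage. Ces1g was 9.82-fold higher (3.30 ± 0.12, adjusted p = 1.26e-11), Nqo1 4.43-fold (2.15 ± 0.19), Sptssb 4-fold (2.00 ± 0.30) and the glutathione peroxidase Gpx2 3.2-fold (1.68 ± 0.17). Cyp1a1 was not called and differed from corn oil control by 0.48 ± 0.44. Of 233 genes called, 210 were higher and 23 lower. Of 22 phase II enzymes 13 rose, most of them glutathione S-transferases such as Gsta2 (1.39 ± 0.16) and Gsta3 (0.94 ± 0.10). Of 24 NRF2 targets 13 rose (19 adjusted over the list alone). Both lists passed camera with its preset correlation and not with an estimated one (adjusted p = 0.119 with an estimated correlation for phase II and 0.0516 for NRF2 targets). Of 24 phase I enzymes 7 rose, a call also lost with the correlation estimated (adjusted p = 0.18 with an estimated correlation).

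Further rises with benzofuran included the acyl-CoA synthetase Acsm1 (1.67 ± 0.19), Aldh3a1 (1.45 ± 0.21) and the peroxisomal oxidase Acox2 (1.26 ± 0.14). Genes of cilia were among the 12 largest, Wdpcp (1.29 ± 0.18) and the radial spoke gene Rsph14 (1.24 ± 0.22). All 14 ciliated cell genes had positive values with a median of 0.41, 1 of them called (Tekt4, 0.83 ± 0.17; 7 adjusted over the list alone), and the list missed with its correlation estimated (adjusted p = 0.342 with an estimated correlation). Afp (1.58 ± 0.37) varied widely between the benzofuran arrays (SD 1.20) and lost its call without benzofuran 10 (log2 fold change 0.93) or without any of the corn oil controls. Among the falls, the fibrillar collagen genes Col3a1 (-0.65 ± 0.13) and Col1a2 (-0.66 ± 0.14) were called of 17 extracellular matrix genes (7 lower adjusted over the list alone; adjusted p = 0.117 with an estimated correlation). The proliferation marker Mki67 (-0.96 ± 0.22), the mitotic gene Bora (-0.89 ± 0.17) and Cdk6 (-0.71 ± 0.14) also fell. The cell cycle list did not fall on every array. Its mean, centred by gene, was 0.32 on benzofuran 10, -0.06 on 6 and -0.09 on 8, against 0.1 to 0.34 in corn oil control. Without benzofuran 10 none of its 29 genes was called, though the list had a median of -0.28. It then passed camera at the preset correlation (adjusted p = 8.73e-10) and not with an estimated one (camera adjusted p = 0.238 with an estimated correlation). Mki67 stood 1.03 ± 0.22 higher in corn oil control than in feed control, and its benzofuran mean of 6.99 lay beside the 6.92 of feed control.

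Benzofuran 10 stood apart from all other arrays, at 46.6 on the first principal component where the others lay between -11.8 and 7.8. Its actin control probe sets had the largest 3' minus 5' difference of the 18 arrays (0.91). The count of called genes was 67 without it, 37 without corn oil control 22, 113 without corn oil control 24, 1054 without benzofuran 8 and 5 when only both groups entered the fit. Falls made up more of the calls with array weights (811 higher and 338 lower) and without corn oil control 25 (234 higher and 82 lower). Without benzofuran 10, 10 NRF2 targets (adjusted p = 0.0162 with an estimated correlation), 7 phase II enzymes (adjusted p = 0.0658 with an estimated correlation) and 7 phase I enzymes (adjusted p = 0.153 with an estimated correlation) were called, and none of the ciliated cell or matrix genes. Of the 12 named rises 10 kept their call in every fit that left out 1 array of either group, and none of the 12 named falls did. Lost calls among the falls do not all mean smaller values, as without benzofuran 10 Mki67 was at -0.95, no longer called, and Bora at -0.93, still called.

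**Figure D2:**
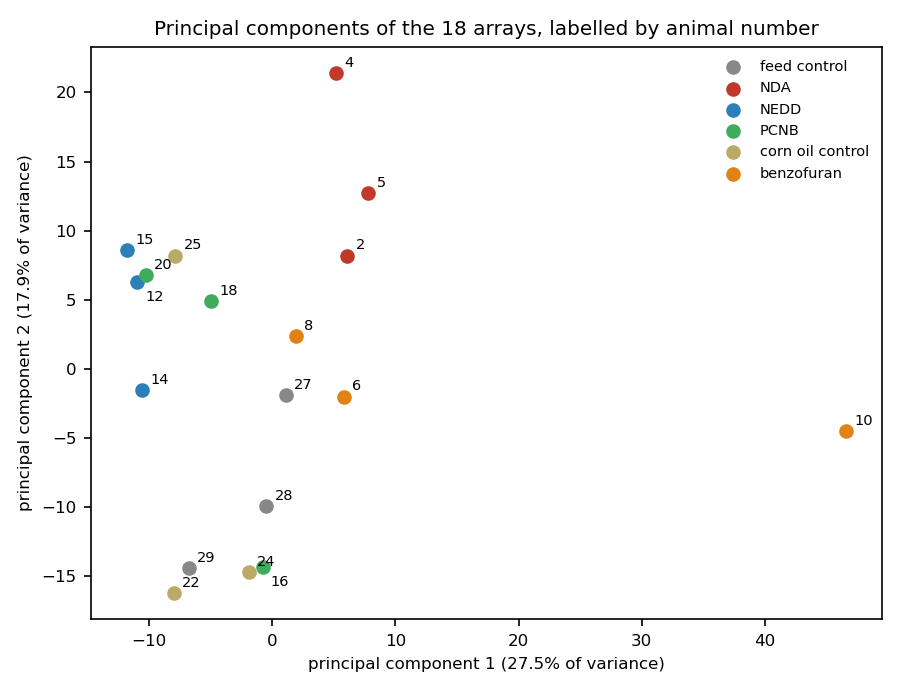
Position of the 18 arrays on the first (horizontal, 27.5% of variance) and the second principal component (vertical, 17.9%), in units of log2 signal, coloured by group and labelled by animal number. Benzofuran 10 lies alone at 46.6 on the first component, and the NDA arrays lie between 8.2 and 21.4 on the second.

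The controls differed in vehicle, route and days of dosing per week, and their comparison gives the background for that difference. No gene was called between corn oil and feed control in limma, and 271 had an unadjusted p under 0.05, fewer than the 672 expected by chance. The absence of calls therefore does not show that the controls were alike. Cell cycle genes lay higher with corn oil in all 29 measured genes, with a median log2 fold change of 0.49, and the list passed (adjusted p = 0.0187 with an estimated correlation, and 16 genes adjusted over the list alone). The mean of the list per array, centred by gene, was -0.37 to -0.15 in feed control and 0.1 to 0.34 in corn oil control. It was -0.02 to 0.02 with NEDD, -0.3 to -0.03 with PCNB, -0.13 to 0.39 with NDA and -0.09 to 0.32 with benzofuran. The difference thus holds a low feed control level as well as a high corn oil level. Racgap1 had a mean of 5.83 in feed control and of 6 to 6.38 in the other groups. The smallest p belonged to Cep55, which acts in cell division (1.17 ± 0.21, adjusted p = 0.247), and to Racgap1 (0.55 ± 0.10, adjusted p = 0.247). Mki67 (1.03 ± 0.22) and Rrm2, a subunit of ribonucleotide reductase (1.08 ± 0.23), followed at an adjusted p of 0.672. Without corn oil control 22 there was 1 gene called.

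Set against each other, the effects of NDA and benzofuran on the lung overlapped. Of the genes that rose with NDA, 50 also rose with benzofuran, where 2.34 would be expected of independent lists, and 2 fell with both (Cdh16 and Gbp3). These comparisons share no control. The shared rises included Ces1g, Nqo1, Sptssb, Gpx2, Fetub, Acox2, Acsm1 and the epithelial chemokine Cxcl17 (1.52 with NDA and 1.07 with benzofuran). Asgr1 was called in opposite directions, -1.32 ± 0.25 with NDA and 1.18 ± 0.25 with benzofuran. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.33 against 0 in simulated unchanged groups. The simulation drew genes independently, so that it does not give the spread of r among unchanged groups of real arrays. Benzofuran gave r = -0.15 with NEDD and -0.03 with PCNB, again without a shared control. Without corn oil control 22 the shared calls numbered 22. NDA and NEDD, which share their feed controls, gave r = 0.32 where unchanged groups gave 0.5 through the shared controls, with a covariance of 0.0156 against a simulated 0.0128. NEDD and PCNB gave r = 0.61 and a covariance of 0.0168 against the same 0.0128. Part of that excess may come from the shared controls, as 3 control arrays are too few to divide.

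**Figure D3:**
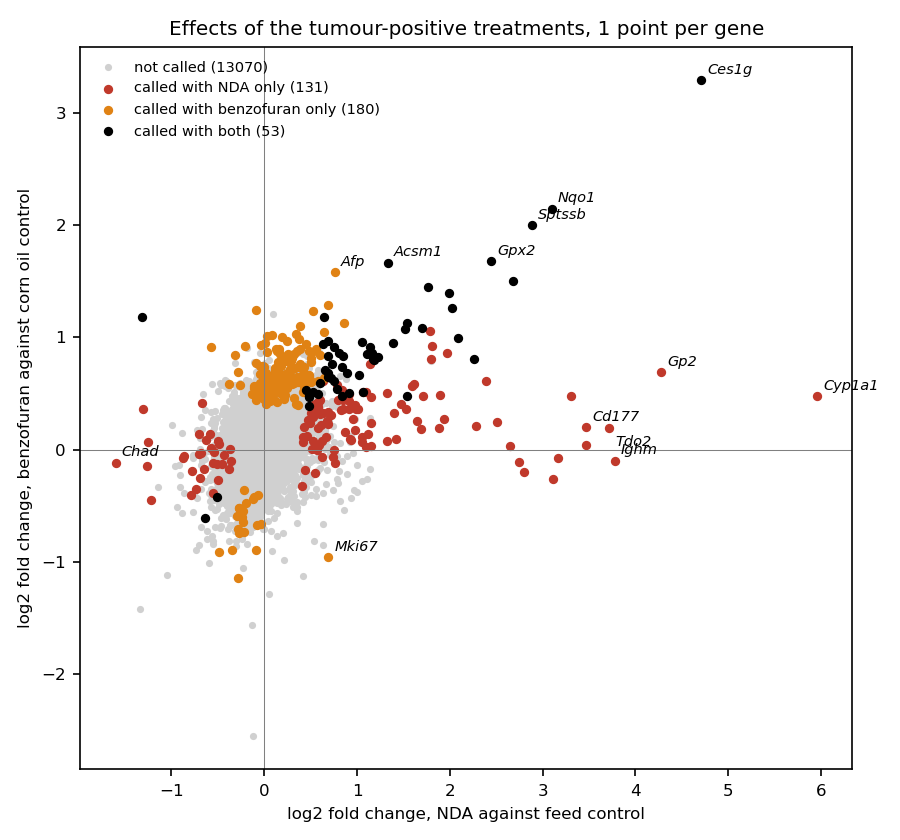
Log2 fold change of each of 13434 genes with NDA against feed control (horizontal axis) and with benzofuran against corn oil control (vertical axis), coloured by which comparison called the gene. Ces1g, Nqo1, Sptssb and Gpx2 lie far up in both, while Cyp1a1, Ighm, Tdo2 and Cd177 lie far along the NDA axis and were not called with benzofuran.

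The central comparison set the tumour-positive treatments against the tumour-negative ones, each treatment relative to its own control. Of 24 NRF2 targets 20 were higher for the positive treatments and none lower (adjusted p = 0.0141 with an estimated correlation). The largest differences were in Ces1g (3.12 ± 0.11, adjusted p = 2.72e-12), Sptssb (2.56 ± 0.26), Gp2 (2.40 ± 0.18), Cd177 (2.21 ± 0.20) and Nqo1 (2.20 ± 0.17). Gp2, Cd177 and Tdo2 (1.89 ± 0.17) owe most of their class difference to NDA, with benzofuran values of 0.69, 0.20 and 0.19. Fetub (1.96 ± 0.16), Gpx2 (1.86 ± 0.14), Gsta2 (1.74 ± 0.14) and Aldh3a1 (1.69 ± 0.18) rose with both positive chemicals. In all, 424 genes were higher and 45 lower.

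Of 22 phase II enzymes 12 were higher in this contrast and of 24 phase I enzymes 11 (adjusted p = 0.119 with an estimated correlation for phase II and 0.18 for phase I). Of 14 ciliated cell genes 8 were higher, among them Capsl (1.06 ± 0.20), Ccdc113 (0.95 ± 0.19) and the ciliogenesis factor Foxj1 (0.73 ± 0.17), a list missed with its correlation estimated (adjusted p = 0.18 with an estimated correlation). The medians behind it were 0.41 with benzofuran and 0.07 with NDA against -0.32 with NEDD and -0.16 with PCNB. The same 8 genes were called without benzofuran 10. Club cell genes had a median of -0.04, with Upk3a (0.83 ± 0.11) and Cckar (0.45 ± 0.12) called. The lower genes included 3 of 19 interferon response genes, Gbp3 (-0.65 ± 0.11), Oasl2 (-0.61 ± 0.11) and Oas2 (-0.54 ± 0.11), with PCNB values of 0.63 for Oas2 and 0.55 for Oasl2 as the largest part of the difference of the latter pair. They also included 3 of 17 matrix genes, Sparc (-0.54 ± 0.09), Col1a2 (-0.52 ± 0.12) and Tnc (-0.75 ± 0.18). Both lists missed with their correlation estimated (adjusted p = 0.159 with an estimated correlation for each). Cdh13, the cadherin that binds adiponectin (-0.80 ± 0.12), and Hlf, a clock-controlled transcription factor (-0.90 ± 0.20), were lower too. All 12 named rises kept their call without any 1 array, and 8 of the 12 named falls. The count was 300 without feed control 28, 868 without benzofuran 8, 308 with the OD260/OD280 ratio of the RNA as a covariate and 1873 with array weights (1322 higher and 551 lower). Each class holds only 2 chemicals, and the standard errors and p-values measure the spread between animals, not between chemicals.

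**Figure D4:**
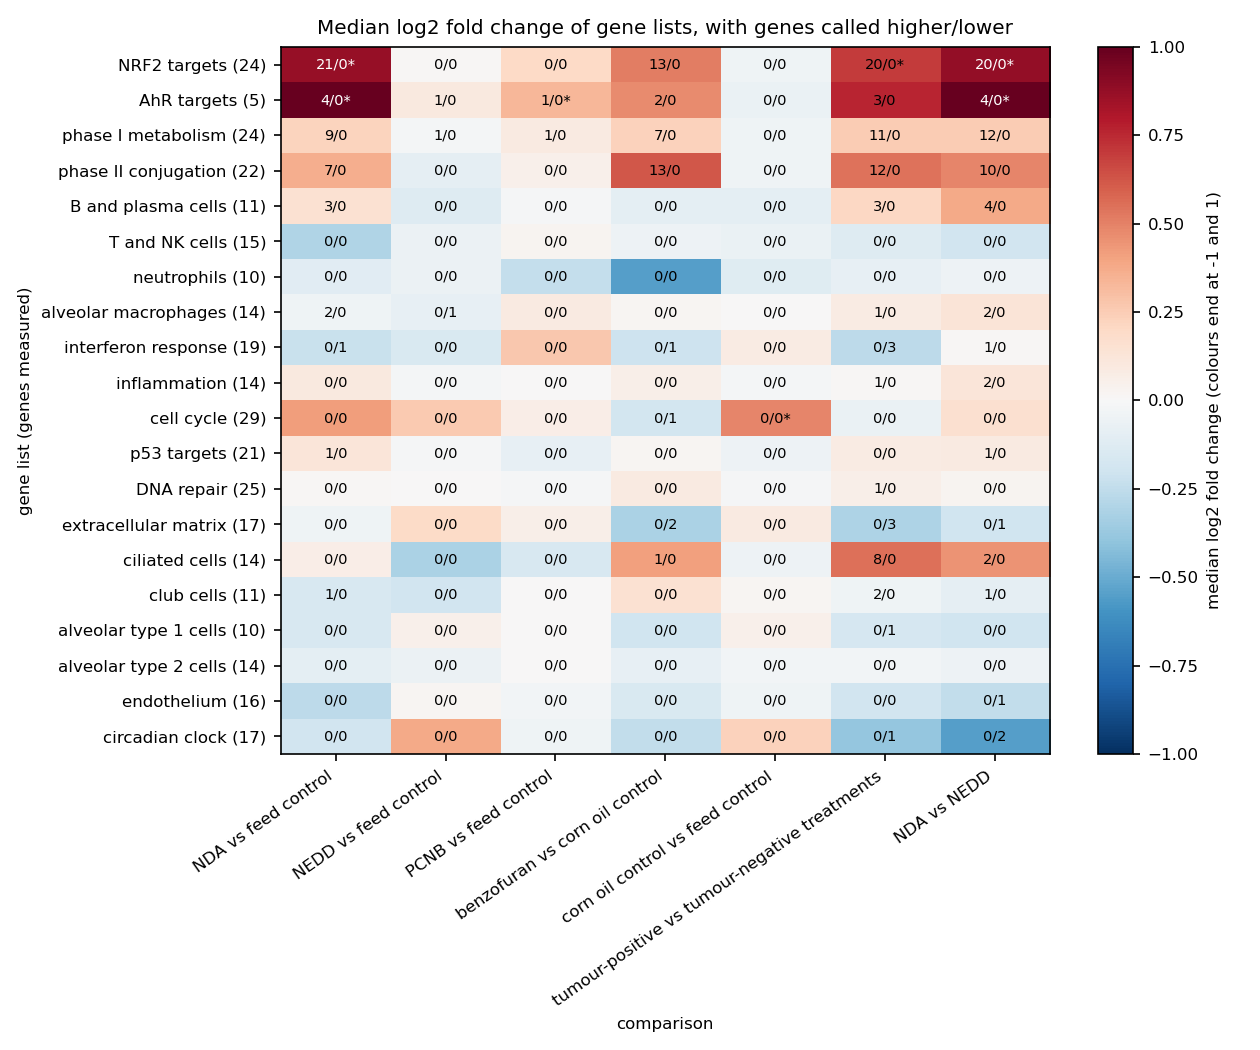
Median log2 fold change (colour) of 20 gene lists (vertical axis, with the number of genes measured) in 7 comparisons (horizontal axis). The numbers give genes called higher and lower, and a star marks lists that passed camera with an estimated correlation, as NRF2 targets do for NDA, for the class contrast and for NDA against NEDD.

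The arrays of both positive groups were also compared with the 12 other arrays, controls included, as in a search for markers that need no matched control. Ces1g was 12.6-fold higher (3.65 ± 0.07, adjusted p = 4.36e-16), and every one of the 6 positive arrays lay above every one of the 12 others. The same held for Sptssb (2.44 ± 0.18), Nqo1 (2.39 ± 0.12), Fetub (2.01 ± 0.11), Gpx2 (1.93 ± 0.10) and Gsta2 (1.68 ± 0.10). In the lower direction it held for Wwox (-0.55 ± 0.11), Cdk6 (-0.50 ± 0.08), Tet2 (-0.46 ± 0.10), Agrn (-0.40 ± 0.10), Myh7 (-0.40 ± 0.06) and the alveolar claudin Cldn18 (-0.37 ± 0.07), all under 1.5-fold. Of 24 NRF2 targets 23 were higher (adjusted p = 0.00645 with an estimated correlation), and of 5 AhR targets 4 (adjusted p = 0.0187 with an estimated correlation). For Cyp1a1 and Cyp1b1 that rests on NDA, as benzofuran means of 7.05 and 7.21 lay below the PCNB means of 9.55 and 7.46. Of 22 phase II enzymes 16 were higher, a list missed with its correlation estimated (adjusted p = 0.111 with an estimated correlation). Without benzofuran 10 there were 14, and the list lay just under the threshold (adjusted p = 0.0456 with an estimated correlation). This contrast called 781 genes higher and 200 lower, of which 201 separated all 6 arrays from all 12. After quantile normalization the split was 650 higher and 290 lower. The count was 606 without NDA 4, 558 without NDA 5 and 1594 without benzofuran 8 and 2660 with array weights (1637 higher and 1023 lower), and 181 of the genes differed by at least 1.5-fold. The standard errors and p-values rest on the spread between animals within groups, not on that between chemicals. The positive class holds only 2 chemicals, and Ces1g means were 10.04 with NDA and 8.99 with benzofuran.

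NDA and NEDD both carry a naphthalene ring bearing nitrogen. NDA has an amino group on each ring, whereas in NEDD a single nitrogen attached to the ring system carries an aminoethyl chain. At the same 2000 ppm in feed for 13 weeks they differed in 285 genes, 253 higher with NDA and 32 lower. NDA gave the higher level of Ces1g (3.95 ± 0.12, 95% interval 3.70 to 4.21), Gp2 (4.22 ± 0.21, 3.77 to 4.67), Cd177 (3.98 ± 0.23, 3.50 to 4.46), Tdo2 (3.72 ± 0.19, 3.31 to 4.12) and Nqo1 (2.81 ± 0.19, 2.40 to 3.21), with adjusted p from 5.48e-13 to 7.69e-08. Both raised Cyp1a1, and NDA did so by 2.73 ± 0.44 more (adjusted p = 0.00112). NRF2 targets were higher with NDA in 20 of 24 genes (adjusted p = 0.0025 with an estimated correlation) and AhR targets in 4 of 5 (adjusted p = 0.00645 with an estimated correlation). Of 11 B and plasma cell genes 4 were higher, Ighm by 3.94 ± 0.48 (adjusted p = 0.159 with an estimated correlation for the list).

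The compounds moved Marco in opposite directions, which left a difference of 2.19 ± 0.16 (adjusted p = 1.15e-07). The neutrophil chemokine Cxcl5 (2.38 ± 0.45) and the cyclooxygenase gene Ptgs2 (1.40 ± 0.29) were higher with NDA. Lower with NDA were Chad (-1.19 ± 0.21), Htr2b (-1.18 ± 0.17), Lrrc26 (-1.17 ± 0.18), the clock gene Per2 (-1.15 ± 0.23), Slc4a5 (-1.08 ± 0.12), the endothelial gene Esm1 (-0.94 ± 0.22) and Cdh13 (-0.84 ± 0.13). Per2 and Bhlhe40 were the called members of 17 clock genes (9 lower and 3 higher adjusted over the list alone; adjusted p = 0.111 with an estimated correlation). All 12 named rises and 8 of the 12 named falls kept their call without any 1 array of either group. The count was 168 without NEDD 12, 189 without NDA 4 and 176 without NDA 5, 507 when only both groups entered the fit and 1813 with array weights (1089 higher and 724 lower).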

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

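The splits, the pairings and the tests of 3' bias and of an untreated animal were written before their results were seen, and the tests of tissue makeup, of ciliated cell genes and of immunoglobulin genes only after the result was seen.

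The effects of NDA and benzofuran differed from each other in 39 genes, a difference between treatments tested with an interaction contrast in limma that was added after seeing the data. Cyp1a1 led it, with an NDA effect larger by 5.48 ± 0.62 on the log2 scale. AhR targets as a list differed as well (adjusted p = 0.0265 with an estimated correlation). Mki67, a marker of dividing cells, had an NDA effect larger by 1.65 ± 0.30. Most of it lies in the controls, as Mki67 was 1.03 higher in corn oil than in feed control, with means of 7.61 for NDA and 6.99 for benzofuran. NDA went into feed and benzofuran by gavage against separate controls, so that chemical, dose, route and vehicle cannot be told apart in this difference.

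Probe sets without a single gene name, outside the genes of the main comparisons, also carried a signal. Of 4424 such probe sets tested, 32 were called with NDA and 13 with benzofuran in limma. Between corn oil and feed control 0 were called, with 76 at an unadjusted p under 0.05.

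Each comparison of 3 arrays with 3 was set beside the 10 ways to split its 6 arrays, and 1 split, the real one, called the most genes in 5 of them. NDA called 184 genes where the highest other split called 0, and NEDD 3, PCNB 2 and NDA against NEDD 285, each against 0. Benzofuran called 233 where the highest other split called 3. Between the controls all 10 of 10 splits called 0 genes. With 10 splits no share under 0.05 is possible.

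For the class contrast 1 of 100 splits, the real one, called 469 genes, and the highest other called 0. For the positive groups against all others 1 of 100 called 981, and the highest other called 9. At a share of 0.05 this argues against an arrangement of the arrays without any group effect. It does not bear on a difference between classes. Splits of single arrays mix a strong treatment into other groups, which widens the pooled spread. Of the 3 ways to pair the 4 treatments, 1 called 469 genes, NDA with benzofuran, followed by NDA with NEDD at 30. Of the 15 pairs of groups, 1 called 981, again NDA with benzofuran, followed by NEDD with PCNB at 212. The 3 pairings and the 15 pairs are too few for a share under 0.05.

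Benzofuran 10 lay far from all other arrays, and a stronger 3' bias could account for it, since its actin 3' minus 5' difference of 0.91 was the highest of 18. Its deviation correlated across genes with the actin slope of the other groups at 0.10, under the 95th percentile of shuffled values of 0.23 (one-sided permutation p = 0.226), which left that explanation open. An animal that had received no benzofuran is argued against, as 57 of 61 benzofuran-induced genes lay above all 12 control and negative arrays in it. A piece of lung with more airway wall remained open, with 5 of 6 lists moving the way it needs and club cell genes (0.01 against 0.13 for all genes) not. A stronger response of this animal to benzofuran, the biological alternative, was not tested.

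Of 14 ciliated cell genes 8 were higher in the class contrast, and the list missed with its correlation estimated (adjusted p = 0.18 with an estimated correlation). None was called with NDA (median 0.07), and values below 0 with NEDD (median -0.32) and PCNB (median -0.16) make up part of the difference. More airway in the pieces sampled would raise club cell genes too. The ciliated median of each array exceeded its club cell median by 0.43 more in the class contrast (95% interval 0.28 to 0.57, t test over arrays), and by 0.38 without benzofuran 10. The ciliated list was examined because it was high in this contrast, so that the interval partly restates that. Of the club cell genes, Cyp2f2 had means of 13.73 with NDA and 13.94 in feed control, while Upk3a rose with NDA. Club cell genes may thus not gauge the airway, and more airway remained open. Loss of club cells was not tested. Benzofuran 10 alone is argued against, as 8 genes stayed called without it. A change in the number of ciliated cells or in their transcripts is the biological alternative and was not tested.

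Ighm, Jchain and Mzb1 rose with NDA, 3 of 11 B and plasma cell genes (adjusted p = 0.227 with an estimated correlation for the list). A single animal is argued against by 9 of 9 tests, since these genes stayed called without each NDA animal in turn. Lymph node tissue in the pieces of lung would bring T cell and B cell surface genes too. The array means of T and NK cell genes, centred by gene, were -0.36 to -0.14 with NDA and -0.06 to 0.14 in feed control. Cd79b and Fcmr of the B cell list had means of 8.42 and 7.63 with NDA against 8.46 and 7.65 in feed control. The B cell surface genes Cd79a and Ms4a1 had small positive values with NDA that did not pass. None of these surface genes neared the rises of 3.78 for Ighm and 3.46 for Jchain. The condition set for arguing against such tissue, which included every T and NK cell gene lower with NDA, was not met. Lymph node or other lymphoid tissue therefore remained open. T and NK cell genes had a median of -0.30 against feed control, but members went both ways (-0.88 to 0.21), with the cytotoxic gene Gzma lowest and the T cell gene Cd3e highest. More plasma cells in the treated lung is the biological alternative and was not tested.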

How the results depend on the processing

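The covariates for log2 OD260 and for actin, the tests of each probe set and the array weights without benzofuran 10 were chosen only after the result was seen.

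With the probe set of highest variance, NEDD called 1 gene and benzofuran 153. A trended and robust prior gave 1 for NEDD. A fit of the compared groups only gave 283 for NDA, 0 for NEDD, 0 for PCNB, 5 for benzofuran and 507 for NDA against NEDD. Array weights gave 755 for NDA, 521 for NEDD, 1149 for benzofuran, 1873 for the class contrast, 2660 for the positive groups against all others, 1813 for NDA against NEDD and 182 shared calls. The OD ratio as a covariate gave 1 for NEDD and 308 for the class contrast. At least 1.5-fold were 243 genes of the class contrast and 181 of the positive groups against all others. Of the 94 list calls, 9 were left with an estimated correlation, and fry made 43.

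The log2 OD260 covariate gave 1 for NEDD. The actin covariate gave 361 for NDA, 1 for NEDD, 718 for benzofuran, 2462 for the positive groups against all others, 632 for NDA against NEDD and 134 shared calls. Tests of each probe set gave 1 for NEDD. Array weights without benzofuran 10 gave 701 for NDA, 469 for NEDD, 400 for benzofuran, 1364 for the class contrast, 1854 for the positive groups against all others, 1787 for NDA against NEDD and 119 shared calls.

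Leaving out 1 array gave 120 to 150 calls for NDA, 0 to 3 for NEDD, 2 to 3 for PCNB, 37 to 1054 for benzofuran, 0 to 1 between the controls, 300 to 868 for the class contrast, 558 to 1594 for the positive groups against all others, 168 to 248 for NDA against NEDD, 22 to 75 shared calls and 81 to 106 list calls.

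Of 113 named results that were called, 62 kept their call in all alternatives in which they were followed, and 0 named results reversed direction there. The fit of compared groups only gives no value for contrasts that use all 6 groups. A log offset was not tried, as the values are already logarithms.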

Other observations

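The tests in this part, limma and camera, were fixed before the result was seen, and the values picked from them and from the principal components were chosen only after.

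Corn oil controls 22 and 24, feed control 29 and PCNB 16 lay together at -16.2, -14.7, -14.4 and -14.3 on the second principal component. Their RNA had OD260 values of 2.902, 2.997, 2.031 and 4.018, the highest of the 18. They come from 3 groups, 2 of them controls. Corn oil controls 22 and 24 are among them and no benzofuran array is, so that whatever sets them apart also enters the benzofuran comparison. That comparison called 37 genes without corn oil control 22 and 113 without 24, against 233 with all arrays. With log2 OD260 as a covariate, 215 of the 233 stayed called among 298.

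The circadian clock genes Per2 and Bhlhe40 were lower with NDA than with NEDD in limma (adjusted p = 0.00882 for Per2), and the list of 17 missed with its correlation estimated (adjusted p = 0.111 with an estimated correlation). The time of day at which tissue was taken is not given in the sources used here.

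Neutrophil genes had negative values with benzofuran in all 10 measured cases, with a median of -0.55 and none called (adjusted p = 0.116 with an estimated correlation). With PCNB the 4 members of smallest p were also lower than in feed control, none of them called. These were S100a8 (-0.81 ± 0.25), S100a9 (-0.82 ± 0.26), Cxcr2 (-0.3 ± 0.11) and Mmp8 (-0.49 ± 0.23).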
